A study of Homo sapiens with 3 samples.

How the data were processed

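RNA-seq of 3 libraries of the human hepatocellular carcinoma line PLC was used, 1 per group: a non-targeting control, shDIS3L2 and shHNRNPU. Per the labels' protocols, cells were harvested 48 hours after infection with hairpin viruses, total RNA was extracted with TRIZOL, purified with a column kit and DNase, and made into libraries with the NEBNext Ultra RNA kit for Illumina. The design text speaks of hairpins in the plural for both targets, and how many were used or pooled is not given in the sources used here. TopHat2 2.0.12, Cufflinks 2.2.1 and genome build hg19 are named per the submitters' processing notes. The library kit is not described as stranded, so a gene and its antisense partner were treated as inseparable.

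The deposited values are FPKM per gene, that is fragments per kilobase of transcript scaled to the mapped fragments of the library, with a lower and an upper bound and a status, per the file headers. The headers do not give the level of the bounds, which were taken as the 95% that Cufflinks uses by default. Per the identifiers in the deposited tables, genes were assembled in each library separately, so locus bounds can differ between libraries and overlapping genes can be merged under several names (2411, 2373 and 2441 merged loci in control, shDIS3L2 and shHNRNPU). Normalization options, masking and the annotation release are not given in the sources used here. An exact 0 can be a failed estimate: 42, 70 and 80 genes were listed at 0 in control, shDIS3L2 and shHNRNPU while both other libraries were at 5 FPKM or more. Such genes are described as listed at 0, and no fold was given for them. The control table held 0 entries on the mitochondrial chromosome, against 11 and 10 in shDIS3L2 and shHNRNPU, so mitochondrially encoded genes entered no comparison (0 of the list matched). Whether this difference also affects the mapped fragments by which FPKM were scaled, and so every ratio against control, is not known.

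No fragment counts are in the tables. For genes with low values, the number of fragments was worked out from FPKM and its interval. Of estimates up to 20 fragments, 66.8%, 71.2% and 67.4% in control, shDIS3L2 and shHNRNPU came out whole within 0.02, too few for a test on counts, so none was run. The FPKM that 1 fragment was worth in single-exon genes of at least 2000 bases (91, 110 and 105 genes) gave depths with medians of 23.0 M (quartiles 22.5 and 23.5), 18.3 M (17.98 and 18.7) and 20.04 M (19.6 and 20.5) fragments. Interval widths show the precision by expression: at a mean FPKM of 1 to 5 they reached a median of 30.1%, 33.0% and 30.3% of the FPKM to either side, and at 50 or more 5.02%, 5.35% and 5.23%.

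Genes were matched across libraries by name. Of 53201 names, 51774 had 1 locus in each library, and for a name with several loci the one with the highest mean FPKM was used. Of these, 11061 had a mean FPKM of at least 1, among them 673 listed at 0 in at least 1 library and 1327 loci with several names, 591 of which join 2 or more protein-coding genes. Log2 ratios were computed as log2 of FPKM plus a pseudocount of 1, which understates the change of genes with low values, and FPKM were used as deposited. A gene passed the size rule when this log2 ratio was at least 1 or at most -1, the deposited intervals of the 2 libraries did not overlap and the status was OK in both. With 1 library per group there is no test across conditions, and no p-value was computed.

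Gene lists for 38 pathways, complexes and cell types were fixed before the data were examined, as were the groups, the size rule, the rule for named genes and a set of other settings. A list's median log2 ratio, over members with a mean FPKM of at least 1, was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5, which describes these libraries only. The named genes were DIS3L2, HNRNPU and RAC1, the 10 genes with the highest and the 10 with the lowest log2 ratio in each knockdown against control (at least 5 FPKM in the higher library and a locus of at least 300 bases), up to 3 members per list past the size rule with the largest ratios, and the 8 genes per direction past the rule in both knockdowns and 5 per order in opposite directions with the largest smaller ratio. Genes of unsure function or of near-identical families could be left out. A few named genes and 1 of the lists are not reported here. Without a further condition, 10, 10, 9 and 10 of the 10 highest and 10 lowest genes in shDIS3L2 and shHNRNPU had a library listed at 0, so after the data were seen the 10 were taken among genes above 0.

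For genes past the rule in both knockdowns, the overlap of independent lists was computed from each list's size. Unchanged libraries sharing 1 control were simulated 200 times, with the spread taken from the deposited intervals or set equal to the observed spread. The other settings were pseudocounts of 0.1 and 5, filters on FPKM, thresholds of 1.5-fold and 3-fold, no interval requirement, median-of-ratios and upper-quartile rescaling, values summed per name, short loci left out, random lists without matching, the mean in place of the median of a list and Spearman's correlation. After the data were seen, genes listed at 0 were also left out. Counts were also repeated over genes above 0 in every library with locus bounds within 100 bases of each other and no overlapping expressed gene. Of these genes, 6294 had a mean FPKM of at least 1.

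The calculations were tested on simulated data for each comparison, with 10388 genes of which 200 were changed, 50 at each fold. The spread came from the deposited intervals, which the size rule also uses, and variation between cultures was not simulated. Few calls among unchanged genes therefore follow from the setting and are not error rates of the real comparisons. In shDIS3L2 against control, 0%, 26%, 88% and 90% of genes changed 1.5-, 2-, 3- and 4-fold were called, and 4 of 10188 unchanged genes. In shHNRNPU against control the values were 0%, 22%, 90% and 84% with 10 unchanged genes called, and in shHNRNPU against shDIS3L2 0%, 30%, 80% and 86% with 6. Of 400 unchanged lists of 25 genes, 5.75%, 4% and 4.5% stood apart in the same order of comparisons. The unchanged lists were random draws, so shares of this size follow from the percentile bounds. A further 400 lists were drawn from the observed ratios, not the simulated ones, and shifted by 0.5 on the log2 scale. Of these, 92%, 94.75% and 84.5% stood apart as higher. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Gene classes and the number of exons per gene were taken from the GENCODE release 29 annotation, whose coordinates, on another build, were not used. Coordinates are those of the deposited tables (hg19), 1-based.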

Results

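RNA was sequenced from PLC cells, an established human hepatocellular carcinoma line, harvested 48 hours after infection with viruses that carried short hairpin RNAs. There were 3 groups of 1 library each. The control library received a non-targeting hairpin, the shDIS3L2 library hairpins against DIS3L2, an exoribonuclease that degrades uridylated RNA from its 3' end, and the shHNRNPU library hairpins against HNRNPU, which encodes the nuclear RNA-binding protein hnRNP U. The study asked how DIS3L2 acts in liver cancer through alternative splicing mediated by hnRNP U. The values were FPKM per gene, which do not resolve the isoforms that splicing yields. From single-exon genes, depth was estimated at 23.0 M fragments for control, 18.3 M for shDIS3L2 and 20.04 M for shHNRNPU. The deposited 95% interval of a gene reached a median of 10.7%, 11.6% and 11.3% of its FPKM to either side in control, shDIS3L2 and shHNRNPU. Across 10388 genes above 0 in every library with a mean FPKM of at least 1, log2 FPKM correlated at 0.950 between control and each knockdown and at 0.936 between the knockdowns. There were no replicates, so no difference below has a replicate check or a p-value. A gene was called higher or lower when its log2 ratio of FPKM plus 1 was at least 1 or at most -1 and the deposited intervals of the libraries did not overlap. A range in parentheses directly after an FPKM is its deposited interval, which covers the estimate within 1 library and not the variation between cultures. Where a gene's name is followed by a pair of FPKM in parentheses, control comes before the knockdown, and a single number there is the log2 ratio against control.

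The targeted genes were measured as a check on the labels. DIS3L2 stood at 7.61 FPKM (6.70 to 8.53) in control, 3.23 (2.31 to 4.15) in shDIS3L2 and 11.2 (10.0 to 12.4) in shHNRNPU. Its log2 ratio against control was -1.03 in shDIS3L2 and 0.50 in shHNRNPU. The locus, on chromosome 2 at 232825955 to 233209060 (hg19), was merged with the overlapping AC068134.10, and its assembled bounds differed between libraries. HNRNPU, merged with its antisense gene HNRNPU-AS1 on chromosome 1 at 245003940 to 245027858, stood at 178 FPKM (172 to 184) in control, 232 (224 to 241) in shDIS3L2 and 33.5 (31.8 to 35.2) in shHNRNPU. Its log2 ratio was -2.38 in shHNRNPU and 0.38 in shDIS3L2. RAC1, a small GTPase whose splicing the study examined, is at chromosome 7, 6414154 to 6443608. Its gene-level value was 368 FPKM (354 to 382) in control, 672 (647 to 697) in shDIS3L2 and 590.5 (568 to 613) in shHNRNPU. These log2 ratios of 0.87 and 0.68 lay below the size rule, although the intervals of both knockdowns lay above that of control.

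**Figure D1:**
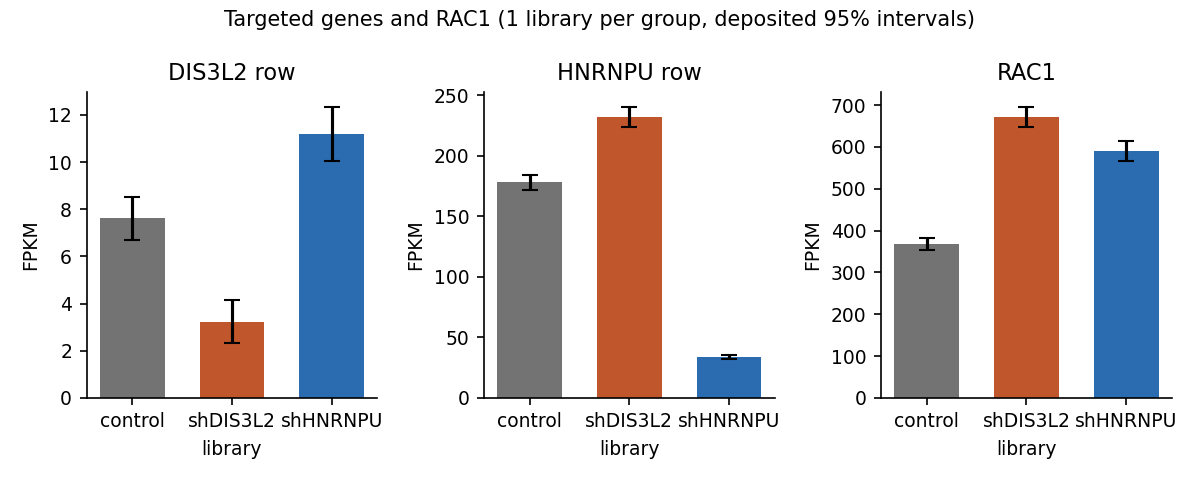
FPKM (linear axis from 0) of the DIS3L2 locus, the HNRNPU locus and RAC1 in the control, shDIS3L2 and shHNRNPU libraries, 1 library per bar, with the deposited 95% intervals as error bars. Each targeted locus was lowest in its own knockdown, at 3.23 FPKM for DIS3L2 and 33.5 FPKM for HNRNPU.

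Knockdown of DIS3L2 was compared with control to ask which transcripts differ when this nuclease is reduced. The median of transcripts of proteins that hepatocytes secrete stood below random lists of like expression in shDIS3L2, with 15 of 28 past the size rule as lower. The medians of mesenchymal and matrix genes (11 of 19 higher), inflammatory genes (9 of 16), integrated stress response genes (5 of 19) and immediate early genes (10 of 24) stood above them. APOA1, the main protein of high-density lipoprotein, stood at 18.9 FPKM (16.6 to 21.3) against 311 (299 to 324) in control. Among single genes on none of the lists, FLNA, the actin crosslinker filamin A, stood at 984 FPKM (949.6 to 1019) against 118 (114 to 121). In all, 1046 genes were higher and 820 lower, and 777 higher and 547 lower once genes listed at 0 in either library were left out. After median-of-ratios rescaling the split turned to 872 higher and 967 lower.

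Of 28 measured hepatocyte secreted proteins, 15 were lower, 1 was higher and 12 passed neither way, with a median log2 ratio of -1.25. That median stood below all 10000 random lists of like expression. Besides APOA1 (log2 ratio -3.97, chromosome 11, 116706467 to 116708666), the lower members included the neighbouring APOC3 (109 to 7.59 FPKM, log2 ratio -3.67) and the acute-phase protein genes ORM1 and ORM2 (-3.30 and -3.33), a pair of near-identical genes. Hepatic transcription factors and enzymes were lower in 8 of 22, higher in 1 and neither in 13, with a median of -0.49. The largest difference there was G6PC, the glucose-6-phosphatase of gluconeogenesis (chromosome 17, 41052814 to 41065386), at 0.140 FPKM (0 to 0.492) against 27.2 (25.5 to 28.9). The hepatic transcription factors CEBPA and ONECUT1 had log2 ratios of -1.43 and -1.82. Also among the 10 lowest genes were NUPR1, a stress-induced transcriptional regulator (226 to 17.9 FPKM, -3.59), SERPINF2, which encodes alpha-2-antiplasmin (504 to 56.4 FPKM, -3.14), AHSG, which encodes fetuin-A (20.9 to 1.49 FPKM, -3.14), and FXYD3 (12.2 to 0.323 FPKM, -3.32).

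Among 19 mesenchymal and matrix genes, 11 were higher, 0 lower and 8 neither, with a median of 1.03. The urokinase gene PLAU (chromosome 10, 75668935 to 75677255) was at 67.0 FPKM (63.3 to 70.6) against 6.23 (5.27 to 7.19), a log2 ratio of 3.23. CD44, a hyaluronan receptor, and the integrin gene ITGA2 had log2 ratios of 1.80 and 1.53. COL5A1, the 1 measured marker of fibroblasts and stellate cells, stood at 2.06 FPKM against 2.41 in control. NF-kB and inflammatory genes were higher in 9 of 16 and neither in 7 (median 1.06). They included the apoptosis inhibitor BIRC3 (1.67) and the chemokines IL8 (61.5 to 181 FPKM, 1.54) and CCL20 (88.6 to 257 FPKM, 1.53). YAP and TEAD targets were higher in 5 of 18 and neither in 13 (median 0.62), led by ANKRD1 (1.73 to 20.05 FPKM, 2.95). Immediate early genes were higher in 10 of 24, lower in 1 (NR4A1, log2 ratio -1.36) and neither in 13 (median 0.71). DUSP5, a phosphatase of ERK, was at 61.9 FPKM against 8.08 (2.79), the transcription factor KLF4 at 20.7 against 4.27 (2.04) and JUN at 41.6 against 12.9 (1.61).

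The integrated stress response list had 5 of 19 genes higher, 1 lower (NUPR1) and 13 neither, with a median of 0.86. Its transcription factor ATF3 was at 26.1 FPKM (23.98 to 28.1) against 2.41 (1.69 to 3.13), and CHAC1, which degrades glutathione, at 94.4 against 28.6. Host genes of small nucleolar RNAs and other transcripts known to be removed by nonsense-mediated decay were higher in 4 of 19 and neither in 15 (median 0.68). These included CDKN1A, the cell cycle inhibitor p21 (7.53 to 36.7 FPKM, 2.14), GADD45A (1.81) and SNHG6 (269 to 785 FPKM, 1.54). Histone genes were higher in 7 of 18 and neither in 11 (median 0.87), led by HIST1H3B (3.25) and HIST1H2BJ (2.17). DNA replication and S phase genes had a median of -0.37, with 3 of 30 lower, among them GINS2 (-1.22) and MCM2 (-1.05), 1 higher and 26 neither, or 2 lower and 0 higher without members listed at 0. Cholesterol synthesis genes had a median of -0.43, with 2 of 22 lower, among them LSS, the lanosterol synthase (-1.34), 1 higher and 19 neither. By the mean of its members this list did not stand apart (percentile 4.61). Of 5 structured small RNAs, RN7SL1, the RNA of the signal recognition particle, was lower (2519 to 986 FPKM, -1.35) and 4 passed neither way, with a median of -0.71. That median was the ratio of RMRP, whose intervals overlapped (14.6 to 37.4 FPKM in control, 4.80 to 26.1 in shDIS3L2). Those of RN7SK and SNORD3A overlapped as well. The random lists were matched on FPKM and not on interval width, so the place of this list is less certain.

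Those 12 lists stood apart from random lists of like expression, 7 on the higher and 5 on the lower side. Of the 35 lists with at least 3 members, 1.75 would do so if their members were random genes. Members of a list can vary together between cultures, so 12 against 1.75 is not a test. Some lists also share genes, such as CDKN1A on the decay-sensitive and p53 lists. Glycolysis and hypoxia genes (3 higher, 2 lower of 24, median -0.14, percentile 2.88) lay just inside the bounds, and stood apart as lower without members listed at 0 (percentile 1.71), with like bounds and no overlapping gene (1.49) and at a mean FPKM of at least 5 (1.74). NRF2 targets (2 higher, 3 lower of 18, median -0.16) stood apart as lower only over the 12 with like bounds and no overlapping gene (percentile 1.27). Apoptosis regulators did not stand apart (median 0.16), with 8 of 24 higher, among them BCL2A1, an anti-apoptotic relative of BCL2 (0.349 to 16.0 FPKM, 3.66), and 1 lower. Nor did p53 targets (6 higher and 1 lower of 16, median 0.25), whose median was 0.47 (percentile 97.4) without members listed at 0, the lower gene among them, and which stood apart as higher at a mean FPKM of at least 5 (1.17 over 9 genes). Nor did let-7 and IGF genes (3 higher and 1 lower of 19, 0.38), ribosomal proteins (2 higher of 68, 0.21), nuclear-encoded oxidative phosphorylation genes (7 higher and 1 lower of 57, 0.15) or endoplasmic reticulum chaperones (3 higher of 19, 0.24). Reference genes for RNA levels had 2 of 20 higher, among them ACTB (1.41), and a median of 0.17. Among the single highest genes were also the keratin gene KRT81 (7.90 to 116 FPKM, 3.72), CHODL (0.0722 to 8.19 FPKM, 3.10) and FHL2 (0.374 to 9.42 FPKM, 2.92).

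The median log2 ratio of all genes above 0 was 0.11 here and 0.13 in shHNRNPU, and 0.00 in both after median-of-ratios rescaling. A list's percentile is relative to that shift. Without members listed at 0, 14 hepatocyte secreted proteins were lower, and 9 immediate early genes, 4 integrated stress response genes and 3 host genes and other decay-sensitive transcripts higher, and each list still stood apart. The assembled bounds of HIST1H3B, HIST1H2BJ, ONECUT1 and ITGA2 differed between libraries. ONECUT1, ITGA2, KRT81, GINS2, MCM2, RN7SL1 and ACTB overlapped another expressed gene, so the values of all these genes are less certain. CEBPA, LSS, SNHG6 and ACTB were each merged with a second overlapping name.

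**Figure D2:**
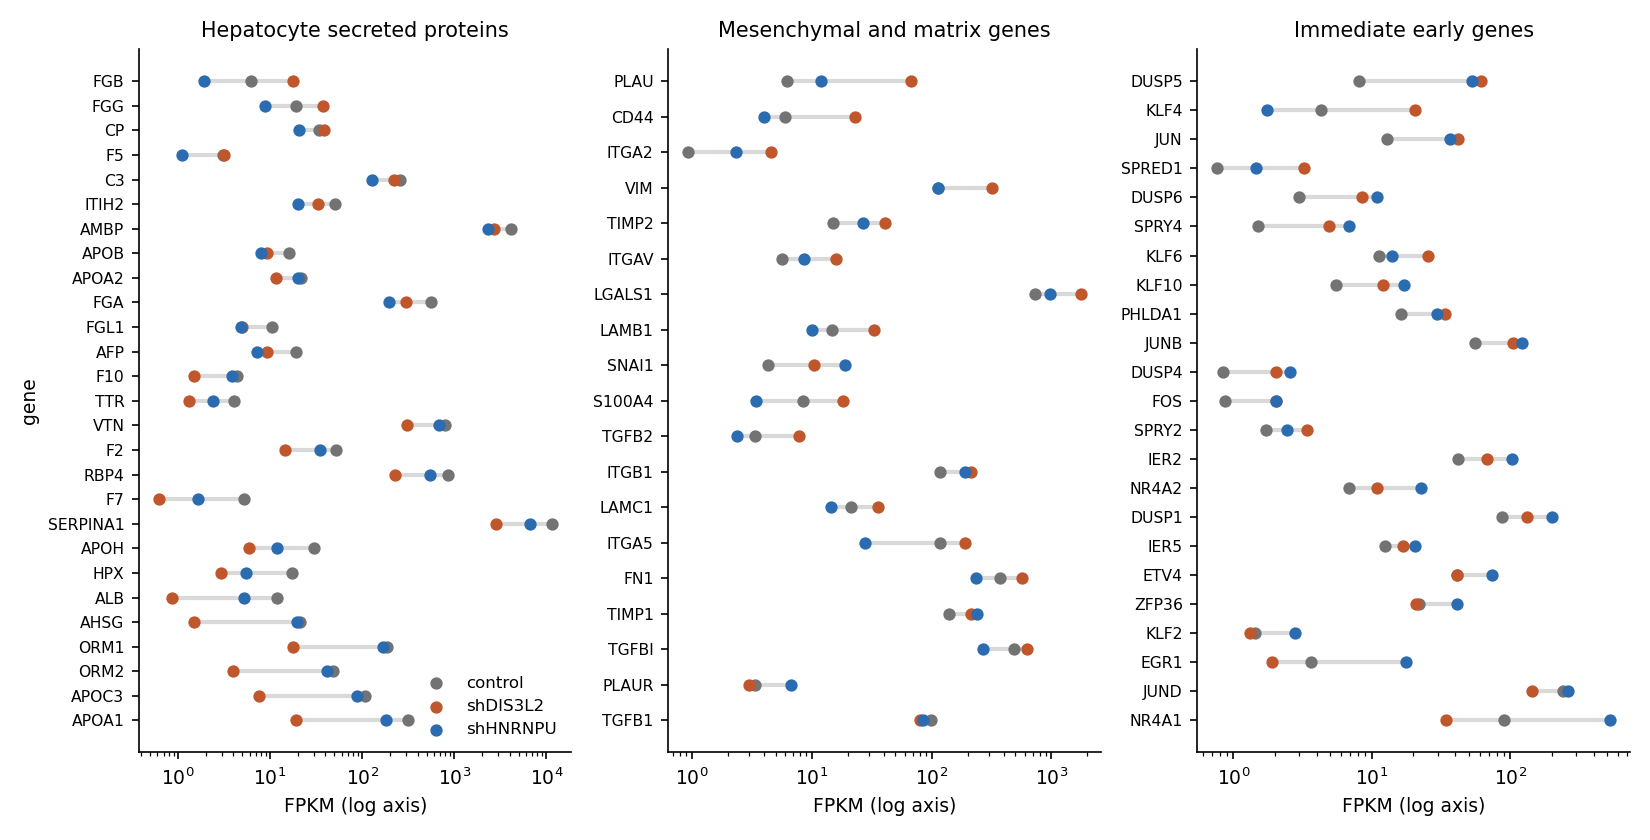
FPKM (log axis) of each member above 0 of the hepatocyte secreted protein, mesenchymal and matrix, and immediate early gene lists, 1 point per library (grey control, orange shDIS3L2, blue shHNRNPU) joined by a line per gene, ordered by the ratio of shDIS3L2 to control. APOA1 lies at 311, 18.9 and 184 FPKM and PLAU at 6.23, 67.0 and 11.9 FPKM in control, shDIS3L2 and shHNRNPU.

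Knockdown of HNRNPU was compared with control to ask which transcripts differ when hnRNP U is reduced. The medians of immediate early genes (12 of 24 past the size rule as higher) and YAP and TEAD targets (5 of 18) stood above random lists of like expression in shHNRNPU, and those of hepatocyte secreted proteins (10 of 28 lower), ribosomal protein genes (2 of 68) and NRF2 targets (4 of 18) below. NR4A1, a nuclear receptor induced within minutes by growth signals, stood at 526 FPKM (506 to 547) against 89.9 (83.9 to 95.9). FGA, the fibrinogen alpha chain, stood at 195 FPKM (187 to 204) against 564 (539.9 to 588). In all, 920 genes were higher and 824 lower, and 691 higher and 545 lower without genes listed at 0. After median-of-ratios rescaling the split was 716 higher and 994 lower, and with a pseudocount of 5 it was 341 and 436.

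Immediate early genes were higher in 12 of 24, lower in 0 and neither in 12, with a median of 1.03. Besides NR4A1 (log2 ratio 2.54) they included DUSP5 (53.3 FPKM against 8.08, 2.58, chromosome 10, 112257596 to 112271302) and the transcription factor EGR1 (17.5 against 3.67, 1.99). YAP and TEAD targets were higher in 5 of 18 and neither in 13 (median 0.60), with the matricellular gene CYR61 at 465 FPKM (445 to 485) against 126 (120.5 to 131) and AMOTL2 at 55.4 against 19.9. Glycolysis and hypoxia genes were higher in 7 of 24, or 5 without those listed at 0, and neither in 17 (median 0.38). They included ADM, which encodes adrenomedullin (16.5 to 88.2 FPKM, 2.35), PFKP (1.35) and BNIP3L (1.23). Apoptosis regulators were higher in 5 of 24, lower in 3 and neither in 16 (median 0.45), with BBC3 higher (1.57) and CASP9 (-1.54) and cytochrome c, CYCS (-1.51), lower. NF-kB and inflammatory genes had a median of 0.51 with 0 of 16 past the rule. Histone genes had a median of 0.77 with 3 of 18 higher, 1 of them above 0 in every library (HIST2H2BE, 1.69), and 15 neither.

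Hepatocyte secreted proteins were lower in 10 of 28, higher in 0 and neither in 18, with a median of -0.88. FGA (-1.53), the haem carrier hemopexin, HPX (17.1 to 5.52 FPKM, -1.48), and alpha-fetoprotein, AFP (19.02 to 7.15 FPKM, -1.30), were among them. APOA1 was at 184 FPKM (175 to 193), a log2 ratio of -0.76, and passed neither way. Ribosomal protein genes had a median of -0.28, below all 10000 random lists, with RPS4X (-1.10) and RPS27A (-1.08) lower and 66 of 68 neither. NRF2 targets were lower in 4 of 18 and neither in 14 (median -0.46). They included the aldo-keto reductases AKR1C1 (265 to 36.4 FPKM, -2.83) and AKR1C2 (-2.35), whose near-identical sequences can share reads, and the glutathione peroxidase GPX2 (11.8 to 2.17 FPKM, -2.01). Of 4 measured blood cell markers, 3 were higher and 1 lower (median 1.97). The haemoglobin genes HBA1 (8.94 to 44.9 FPKM) and HBA2 (8.25 to 36.2 FPKM), near-identical copies, were higher and lysozyme, LYZ (181 to 70.8 FPKM), was lower.

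In all, 11 of the 35 lists stood apart, 8 higher and 3 lower. Hepatic transcription factors and enzymes did not (5 of 22 lower, 1 higher, median -0.12, percentile 5.37), although G6PC (2.18 FPKM, -3.15) and CEBPA (19.9 FPKM, -1.80) were lower, and the list stood apart as lower by the mean of its members (percentile 2.22), at a mean FPKM of at least 5 (0.52) and without an expression filter (0.86). Nor did cholesterol synthesis genes (4 of 22 lower, median -0.15), mitosis genes (4 of 28 higher, median 0.27, with TOP2A at 1.75 and KIF11 at 1.12), integrated stress response genes (4 higher and 1 lower of 19, -0.05) or matrix genes (1 higher and 2 lower of 19, 0.00), but some of these calls changed with the members used. With like bounds and no overlapping gene, 13 matrix genes (0.43) and 8 p53 targets (0.71, against 0.09 over all 16) stood apart as higher and 16 cholesterol synthesis genes (-0.25, percentile 1.85) as lower. Mitosis genes stood apart as higher by the mean of their members (percentile 98.6), let-7 and IGF genes at a mean FPKM of at least 5 (99.3) and without an expression filter, and heat shock genes at a mean FPKM of at least 5 (98.1). That mean of the mitosis genes includes 1 member listed at 0 in a library, and without it their median was at percentile 77.4. SNAI1, a repressor of E-cadherin, was the higher matrix gene (1.93) and the integrin gene ITGA5 was lower (118 to 28.0 FPKM, -2.03).

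Among the single genes that differed most, ROCK1, a kinase of the actin cytoskeleton, was at 20.5 FPKM (18.7 to 22.3) against 2.10 (1.57 to 2.63). ALG14, an enzyme subunit of N-glycan synthesis, was at 24.96 FPKM (20.6 to 29.3) against 2.35 (1.67 to 3.02), and C1orf64 at 38.3 (32.9 to 43.8) against 0.978 (0.736 to 1.22). The cancer-testis gene MAGEC2 was at 12.97 against 0.997 (2.81), and VCX3A, VCX3B and VCX, near-identical X-linked testis genes, had log2 ratios of 3.54, 3.29 and 2.84. Lowest were NUPR1 (226 to 16.4 FPKM, -3.71), carbonic anhydrase 2, CA2 (99.3 to 8.35 FPKM, -3.42), MCCC2 of leucine breakdown (26.8 to 1.85 FPKM, -3.29), TRNAU1AP of selenoprotein synthesis (54.6 to 3.602 FPKM, log2 ratio of -3.6) and CCDC28B (34.0 to 3.70 FPKM, -2.90).

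NF-kB genes and apoptosis regulators no longer stood apart when the mean of the members replaced the median (percentile 88.1 for apoptosis regulators). Apoptosis regulators and histone genes no longer did at a mean FPKM of at least 5, NF-kB genes, apoptosis regulators and blood markers without an expression filter, and glycolysis genes without members listed at 0 (percentile 97.2), with like bounds and no overlapping gene (96.7) and against random lists not matched on expression (96.7). Without members listed at 0, 11 immediate early genes, 3 mitosis genes and 2 blood markers were higher and 9 hepatocyte secreted proteins lower. Assembled bounds of TRNAU1AP, CASP9 and CYCS differed between libraries, and TRNAU1AP, NR4A1, RPS4X, GPX2 and LYZ overlapped another expressed gene.

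**Figure D3:**
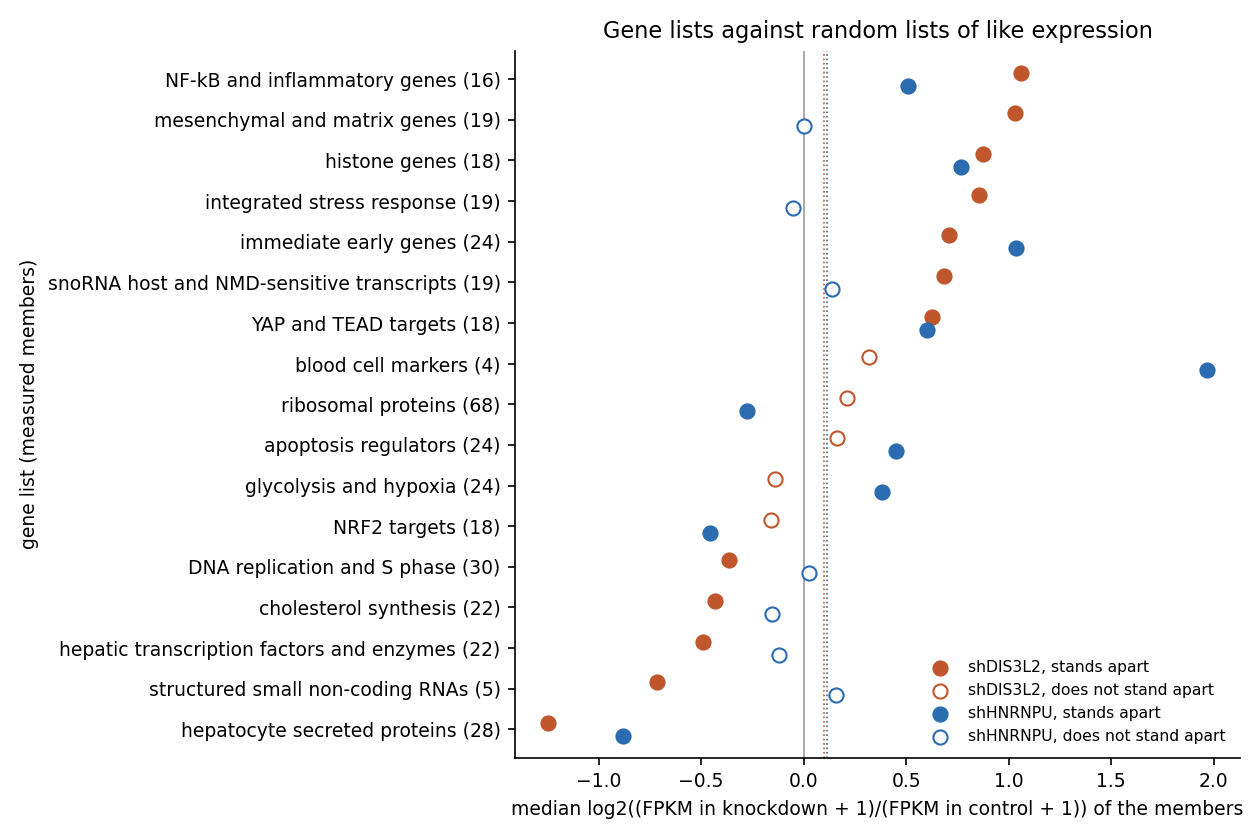
Median log2 ratio (FPKM plus 1) of 17 gene lists that stood apart in at least 1 knockdown, shDIS3L2 in orange and shHNRNPU in blue against control, with the number of measured members in parentheses. Filled circles stand apart from 10000 random lists of like expression, open circles do not, and dotted lines mark the median of all genes with a mean FPKM of at least 1. Hepatocyte secreted proteins lie at -1.25 and -0.88, matrix genes at 1.03 and 0.00.

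Genes of the splicing and RNA decay machinery were examined because both targets act on RNA. No splicing or decay factor list stood apart in either knockdown. In the hnRNP family, HNRNPU itself not counted, 0 of 17 genes passed the size rule in either knockdown, with medians of 0.04 in shDIS3L2 and 0.10 in shHNRNPU, and of -0.07 and -0.04 after median-of-ratios rescaling. The SR and TRA2 factor list had 1 of 23 higher and 1 lower in each knockdown, the lower one in shDIS3L2 being listed at 0 there. CLK1, a kinase of SR proteins, was at 48.0 FPKM (42.1 to 53.9) in shDIS3L2 and 14.0 (12.3 to 15.7) in shHNRNPU against 6.85 (5.65 to 8.05) in control, and passed the rule in shDIS3L2 alone. In shHNRNPU the SR protein kinase SRPK2 was higher (6.27 to 23.9 FPKM, 1.77) and SRSF5 lower (86.7 to 41.1 FPKM, -1.06). Core spliceosome genes had 2 of 36 higher and 1 lower in each. SNRPD1, a core Sm protein, was at 68.3 FPKM in shDIS3L2 and 68.5 in shHNRNPU against 216 in control, CRNKL1 was higher in both (1.91 and 1.10), and SNRPF was higher in shHNRNPU (61.4 to 256 FPKM, 2.04). Regulators of tissue-type splicing had 4 of 27 higher and 1 lower in shDIS3L2 and 3 higher and 1 lower in shHNRNPU. PTBP2 (3.79 FPKM in control, 14.8 and 9.96 in shDIS3L2 and shHNRNPU) and NOVA1 (1.02, 5.04 and 4.64), both known from neurons, were higher in both. MBNL1 was higher in shDIS3L2 (1.20), and EWSR1 was lower in shHNRNPU (219.7 to 48.6 FPKM, -2.15). Of 32 genes of the exosome and 3' decay, 0 passed the rule in shDIS3L2, and in shHNRNPU DIS3 was higher (1.22) and EXOSC2 lower (-1.37). Of 15 nonsense-mediated decay factors, 0 passed in shDIS3L2 (median 0.22). The host genes and other decay-sensitive transcripts that stood apart in shDIS3L2 had a median of 0.14 in shHNRNPU. RMRP, the RNA of RNase MRP, was at 166 FPKM (128 to 205) in shHNRNPU against 26.01 (14.6 to 37.4), while RN7SL1 was lower there too (2519 to 615 FPKM, -2.03), and the median of the 5 structured small RNAs was 0.16. SRPK2, EWSR1 and DIS3 overlapped another expressed gene, and bounds of NOVA1 and EXOSC2 differed between libraries.

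Both knockdowns were set side by side to see which genes differed from control in the same direction. Those with the largest ratios included EREG, IL11 and DUSP5, higher in both, and NUPR1 and G6PC, lower in both. EREG, a ligand of the epidermal growth factor receptor, was at 2.64 FPKM (2.24 to 3.05) in control, 19.2 (18.03 to 20.3) in shDIS3L2 and 22.4 (21.1 to 23.8) in shHNRNPU. The metallothionein gene MT2A was at 432, 2342 and 1817 FPKM in the same order, RASD1, a RAS-related protein, at 100.4, 374 and 692, the cytokine IL11 at 2.53, 11.3 and 11.4, the small GTPase gene RHOB at 60.6, 228 and 235, and DUSP5 was higher in both, as given above. Lower in both were NUPR1 (chromosome 16, 28548606 to 28550495), G6PC, SERPINF2, corticosteroid-binding globulin, SERPINA6 (238, 44.0 and 33.2 FPKM), the MAP kinase phosphatase DUSP9 (229, 29.3 and 44.5) and the hedgehog ligand IHH (8.42, 0.755 and 0.767). The assembled bounds of IHH and IL11 differed between libraries, and IHH overlapped another expressed gene. Among genes above 0 in every library, the largest ratio in each knockdown was that of C1DP1, a pseudogene of C1D that can share its reads, with intervals as wide as 0 to 30.5 FPKM in control and 1076 to 4849 in shHNRNPU.

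Among 11061 genes with a mean FPKM of at least 1, 236 were higher in both and 235 lower in both, against 71.2 and 49.9 for independent lists of these sizes. Over all matched genes, without that filter, 239 were higher and 279 lower in both, and 194 and 343 after median-of-ratios rescaling. Opposite calls numbered 24 and 21, against 64.2 and 55.3. Both comparisons use the 1 control library, which by itself pairs their differences. Log2 ratios correlated at 0.392 (Pearson) and 0.334 (Spearman) across genes, which are not replicates, with a covariance of 0.3998. In 200 simulated sets of unchanged libraries with the deposited intervals as their spread, the correlation was 0.492, the covariance 0.0673 and the overlaps 0.170 and 0.140 genes. With a spread as large as the observed one shared equally by the libraries, the simulated covariance was 0.550 and the overlaps 448 genes each way. These simulated overlaps used the size threshold without intervals, so they follow a looser rule than the observed ones. Without the interval requirement, the observed overlaps were 269 higher and 326 lower even over all matched genes, still fewer than 448. Over genes above 0 in every library, the observed covariance was 0.174 and the overlaps 149 higher and 134 lower. The equal-spread simulation gave 0.259, 243 and 245 there. The control could not be split, so part or all of the overlap may come from it.

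**Figure D4:**
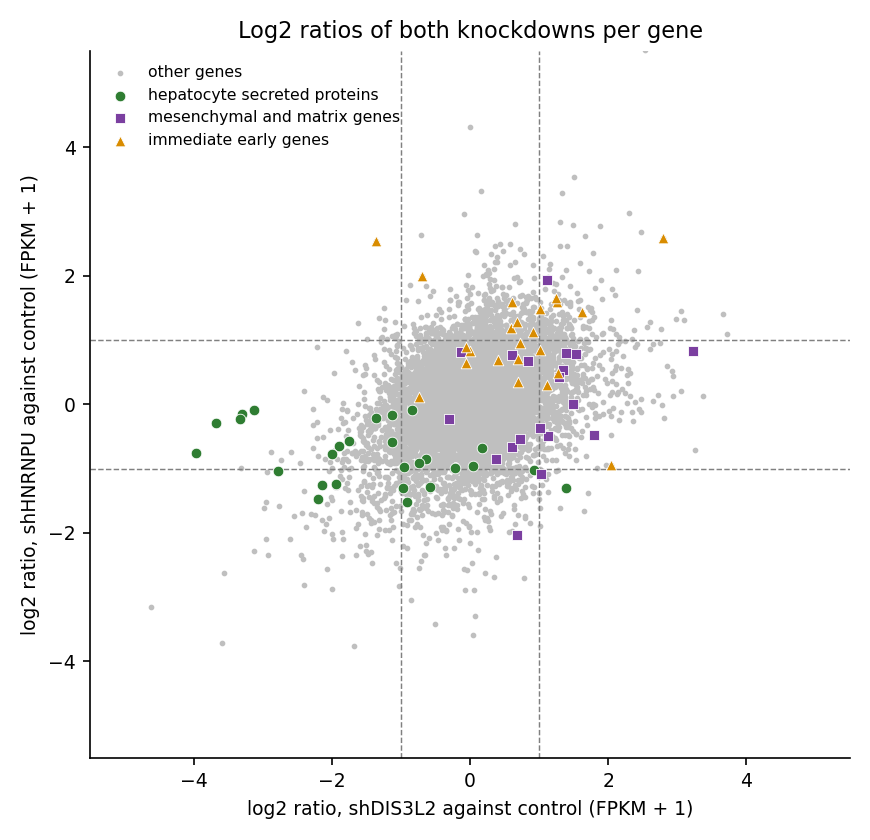
Log2 ratio (FPKM plus 1) against control in shDIS3L2 (horizontal) and shHNRNPU (vertical) for 10388 genes above 0 in every library with a mean FPKM of at least 1, 1 point per gene, with 3 lists coloured and 3 genes outside the axes. Dashed lines mark a log2 ratio of 1 in either direction, beyond which 149 genes were called higher in both and 134 lower in both.

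The knockdowns were also compared directly, without the control. Hepatocyte secreted proteins were higher in shHNRNPU than in shDIS3L2 in 9 of 28, lower in 3 and neither in 16, with a median of 0.71, and APOA1, APOC3, ORM1, ORM2 and AHSG all had log2 ratios of at least 3. Matrix genes were lower in shHNRNPU in 10 of 19 and neither in 9 (median -1.22). The lower ones included ITGA5, PLAU and CD44, with log2 ratios against shDIS3L2 of -2.71, -2.40 and -2.27. Ribosomal proteins were lower in 8 of 68 (median -0.47), integrated stress response genes in 7 of 19 (-0.49), host genes and other decay-sensitive transcripts in 6 of 19 with 1 higher (-0.55) and NRF2 targets in 4 of 18 (-0.54). Histone genes (median -0.44, 4 higher and 3 lower of 18, or 2 higher and 3 lower among those above 0) also stood apart as lower. DNA replication genes (0.39, 5 higher and 1 lower of 30), hepatic transcription factors and enzymes (0.46, 5 higher and 1 lower of 22), glycolysis and hypoxia genes (0.40, 7 higher of 24), structured small RNAs (0.68, 5 measured) and blood markers (1.41, 4 measured) stood apart as higher. DNA replication genes did so no longer without members listed at 0 (percentile 97.3, 4 higher) or with like bounds and no overlapping gene (94.5). By the mean of the members, histone genes (percentile 18.4), hepatic transcription factors and enzymes (87.7), structured small RNAs and host genes and other decay-sensitive transcripts (4.30) no longer stood apart. The median of the structured small RNAs was the ratio of RN7SK, whose intervals overlapped (12.6 to 25.7 FPKM in shDIS3L2, 22.4 to 40.2 in shHNRNPU). In all 1102 genes were higher and 1207 lower in shHNRNPU than in shDIS3L2, 844 and 902 of them above 0 in both libraries.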

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

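All tests of explanations in this part were chosen after the results were seen. The hepatocyte secreted proteins had medians below random lists in both knockdowns, -1.25 in shDIS3L2 (15 of 28 lower, 1 higher) and -0.88 in shHNRNPU (10 of 28 lower). Gene models that differ between libraries, and estimates listed at 0, were argued against by the 24 members above 0 with like bounds and no overlapping gene, whose medians were -1.55 and -0.88. A control library that stands apart from both others cannot account for the shDIS3L2 difference alone, since the median in shHNRNPU against shDIS3L2, without the control, was 0.71. For shHNRNPU it cannot be told apart from an effect of the knockdown, because each comparison with that direction, at -0.88, uses the 1 control. A candidate explanation that remains is lower expression of liver genes after knockdown of each target, which 1 library per group leaves untested.

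Mesenchymal and matrix genes had a median of 1.03 in shDIS3L2, with 11 of 19 higher. Over the 13 members above 0 with like bounds and no overlapping gene the median was 1.11, which argues against differing gene models. Against shDIS3L2, shHNRNPU had a median of -1.22, so a control that stands apart is not needed for the difference. RNA of fibroblasts or stellate cells was argued against, because the highest upper bound of COL1A1, COL1A2 and COL3A1 in shDIS3L2 was 0.765 FPKM, where such cells would bring these collagens in abundance. Knockdown of DIS3L2 may raise these genes, a hypothesis from the same data, and an effect of the 1 culture or of the hairpins used stays open and untested.

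Immediate early genes had medians above random lists in both knockdowns, 0.71 in shDIS3L2 (10 of 24 higher, 1 lower) and 1.03 in shHNRNPU (12 of 24 higher). Over the 13 members above 0 with like bounds and no overlapping gene, the smaller of both medians was 0.70, which argues against differing gene models. Single members differed: DUSP5 and JUN were higher in both, but NR4A1 had log2 ratios of -1.36 in shDIS3L2 and 2.54 in shHNRNPU. EGR1 had -0.69 and 1.99, and KLF4 2.04 and -0.94, opposite signs that a low control alone cannot give. For the list's median, a control library low in immediate early genes cannot be told apart from a shared effect. The median in shHNRNPU against shDIS3L2 was 0.31, and both comparisons use the 1 control. These genes react within minutes to serum and handling, so a difference in harvest may contribute as well as the knockdowns, and neither was tested.

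Of the genes that passed the size rule in opposite directions, those with the largest sizes follow, and for none was the difference between the knockdowns tested. VAT1L had a log2 ratio of 1.65 in shDIS3L2 and -1.66 in shHNRNPU, and the merged locus of BMI1, a Polycomb protein, and COMMD3 1.71 and -1.38. CLU, which encodes the secreted chaperone clusterin, had 1.30 and -1.62. The fibrinogen gene FGB had 1.39 and -1.30, opposite to most other hepatocyte secreted proteins in shDIS3L2. NR0B2, a nuclear receptor that represses bile acid synthesis, had 1.12 and -1.36. In the other order, NR4A1 had -1.36 and 2.54, RTN4RL2 -1.62 and 1.26, the merged locus of ADAP1 and COX19 -1.23 and 1.31, and the transcription factor ZNF263 -1.25 and 1.17. NR0B2, NR4A1 and RTN4RL2 overlapped another expressed gene, so their values are less certain.

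A signal outside the comparisons was a merged mitochondrial locus of 26 names, at 33451 FPKM in shDIS3L2 and 38281 FPKM in shHNRNPU, for which the control table held no entry to compare.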

How the results depend on the processing

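Leaving out genes listed at 0 and keeping genes with like bounds and no overlapping gene were chosen after the data were seen. No paired analysis was possible because each group had 1 library, so none was left out. Upper-quartile rescaling moved none of 236 single-gene ratios beyond their interval. Median-of-ratios rescaling moved 102 and a pseudocount of 0.1 moved 74 of 341 gene and list ratios, and no called value was reversed. In simulated data changes of 2-fold were mostly missed, as the threshold with its pseudocount implies at any depth.

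Genes past the rule (1866 in shDIS3L2, 1744 in shHNRNPU, 2309 between the knockdowns, 518 in both) followed the stringency of each setting. With a pseudocount of 5 they numbered 850, 777, 1092 and 223. At 1.5-fold they numbered 4007, 3963, 4619 and 1408, and at 3-fold 705, 690.0, 884 and 222. With like bounds and no overlapping gene, 760.0, 711, 1003 and 175 of the fewer genes passed. FPKM of at least 1 in every library gave 1141, 1057 and, for both, 240.0. A pseudocount of 0.1 gave 784 in both, and leaving out genes listed at 0 gave 292 in both. Median-of-ratios rescaling gave log2 ratios for HNRNPU of 0.27 in shDIS3L2 and -2.52 in shHNRNPU, and for RAC1 of 0.75 and 0.54, which follows from the factors. Spearman's correlation of the knockdowns' ratios was 0.334. Lists standing apart numbered 11 to 15, 10 to 12 and 8 to 12 in the 3 comparisons. Cholesterol synthesis in shDIS3L2 lost its place with the mean of the members (percentile 4.61). Several lists that did not stand apart did so with other members, among them matrix genes in shHNRNPU (0.43) with like bounds and no overlapping gene, p53 targets in both knockdowns and glycolysis genes in shDIS3L2. The cause was not tested.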

Other observations

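Several gene groups, a few of them described above, did not stand apart from random lists of like expression in either knockdown with the main settings, yet held single genes past the size rule. No tests were made in this part. Epithelial junction and keratin genes had 2 of 18 higher in shDIS3L2, KRT7 (7.04 to 32.2 FPKM) and the tight junction gene TJP1 (5.07 to 11.6 FPKM), with a median of 0.28. In shHNRNPU 1 was higher, CTNNB1, which encodes beta-catenin (62.2 to 131 FPKM), with a median of -0.10. Fatty acid synthesis and lipid storage genes had 4 of 22 lower in shDIS3L2 and 1 higher, with a median of 0.01 that was -0.08 after median-of-ratios rescaling. The lower genes included the desaturases SCD (235 to 81.5 FPKM) and FADS1 (62.2 to 22.9 FPKM) and the glucose-responsive factor MLXIPL (3.59 to 1.02 FPKM), while 0 passed in shHNRNPU (median 0.10). Among interferon-stimulated genes, IFI6 was lower (47.6 to 11.2 FPKM) and ISG20 (23.2 to 65.7 FPKM) and PARP14 (0.589 to 2.45 FPKM) higher in shDIS3L2 (median 0.07 over 16), and in shHNRNPU OAS3 was lower (6.07 to 1.82 FPKM) and HERC5 higher (median -0.02). Assembled bounds of MLXIPL and OAS3 differed between libraries, and MLXIPL, FADS1, KRT7 and CTNNB1 overlapped another expressed gene.

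Heat shock genes had 3 of 18 higher in shDIS3L2 (median 0.16), with the small heat shock protein gene HSPB8 at 28.5 FPKM (26.2 to 30.8) against 4.92 (4.11 to 5.74), and 1 in shHNRNPU (median 0.26), HSP90AA1 (160.2 to 339.9 FPKM). Of 10 Wnt pathway targets, CCND1, which encodes cyclin D1, was higher in shDIS3L2 (37.8 to 95.4 FPKM) and PORCN and ZNRF3 lower (-1.23 and -1.16), and APCDD1 was lower in shHNRNPU (-1.19). Mitosis genes had 1 of 28 higher in shDIS3L2, CENPF (4.44 to 13.1 FPKM, median 0.14). Endoplasmic reticulum chaperones and the unfolded protein response had HERPUD1 (30.0 to 98.2 FPKM), ATF6 (6.08 to 16.7) and DNAJB11 (49.5 to 107) higher in shDIS3L2 and ATF6 (6.08 to 15.3 FPKM) in shHNRNPU. In the let-7 and IGF list, IGF2BP3, an RNA-binding protein of fetal tissue, was higher (4.79 to 15.3 FPKM) and H19 lower (7.83 to 1.54 FPKM) in shDIS3L2, and 0 of 19 passed in shHNRNPU (median 0.42). Of the nuclear-encoded subunits of cytochrome c oxidase, COX7C was higher in both knockdowns (356 FPKM in control, 1485 and 1245 in shDIS3L2 and shHNRNPU) and COX7B lower in both (167, 54.9 and 35.6). Assembled bounds of COX7B differed between libraries, and CCND1 and IGF2BP3 overlapped another expressed gene.

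Markers of other cell types were mostly low. At least 1 FPKM was reached by 3, 4 and 4 of 21 matched blood cell markers in control, shDIS3L2 and shHNRNPU, by 1 of 16 fibroblast and stellate cell markers in each library, and by 0, 1 and 0 of 13 endothelial markers. The endothelial marker was LYVE1, a hyaluronan receptor, at 3.65 FPKM in shDIS3L2 against 0.174 in control, with differing bounds. CA9, a carbonic anhydrase induced by hypoxia and chosen after its values were seen, was listed at 0 in control and shDIS3L2 and stood at 62.0 FPKM in shHNRNPU.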
